A study of Homo sapiens with 27 samples.

How the data were processed

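RNA of HBL-1 and HT cells was measured on 27 Illumina HumanHT-12 BeadChip arrays. The arrays formed 9 groups with 3 replicate arrays each. HBL-1 had DMSO arrays labelled 0 h and arrays after 12, 24, 36 and 48 h of 600 nM cyclosporin A. HT had DMSO arrays labelled 0 h and arrays after 12, 24 and 36 h. Groups were taken from the sample labels.

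The value table deposited by the authors holds log2 intensities, a single value per probe and array. How the authors normalized them is not given in the sources used here. Array medians ran from 4.282 to 4.366 in HBL-1 and from 4.305 to 4.388 in HT, and 95th percentiles from 10.848 to 10.896 and from 11.02 to 11.075. The 75th percentile spread more, from 6.011 to 6.39 in HT. Each line may have been normalized on its own. The deposited bead-level files hold raw intensity per bead, with a bead code and no identifier of the named probes. The value table was therefore the input of every comparison. The bead-level intensities were summarised on the log2 scale as the mean per bead code after leaving out beads beyond 3 median absolute deviations. Median bead numbers per code ran from 19 to 23. Of 47976 probes, 14697 were matched to a bead code by their profile over the arrays, which covered 8982 of 12572 genes tested. That match used the compared values themselves, so it gave no independent check. It served only as an alternative, for counts and in the tallies of named genes and lists.

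Of 48107 probes, 131 with an empty value were left out. A probe was kept when its mean over all 27 arrays was above the median of all probe means, 4.3 on the log2 scale. Gene names came from the probe annotation, updated by gene ID. There were 16954 kept probes with exactly 1 gene symbol. The kept probe with the highest mean stood for its gene, which gave 12572 genes tested. Another 7034 kept probes had no single symbol in that annotation. For folds against values at background, the ceiling of the background was 4.33 in HBL-1 and 4.43 in HT on the log2 scale, and folds were given as lower bounds where every array of a group lay at or below it. Where only some arrays of a group lay above it, their number is given beside many of the largest changes.

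Differences were tested with limma 3.58.1 in R 4.3.3. A linear model held 1 mean per group over all 27 arrays, with 18 residual degrees of freedom, and contrasts of group means were moderated with a trend on mean intensity, which added 18.5 prior degrees of freedom. Tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method within each contrast, at a threshold of 0.05. Errors are limma standard errors of a log2 fold change. The 13 contrasts were each CsA time point against DMSO of the same line, the mean of 12, 24 and 36 h against DMSO in each line, 36 h against 12 h in each line, the difference between the lines in the response to the 12 to 36 h mean, and the lines in DMSO. Nothing in the labels says whether replicates were separate cultures, so the p-values measure the spread between these arrays. The number of arrays limits the precision of every value.

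Gene lists were written before the data were examined, as were the tests, most of the alternatives described next, and the rule for naming genes. There were 32 lists, of pathways, B-cell states and markers of other cell types, and 713 of their genes were tested. Each list was compared with all other genes by limma's camera with an inter-gene correlation of 0.01, adjusted over the 32 lists within each contrast, and again with an estimated correlation. The fry test was run beside it. List tests for the single time points other than 48 h, and for 36 h against 12 h, were added after the data had been seen.

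Genes were named by rule. For the 12 to 36 h means, HBL-1 at 48 h, the line difference and the lines in DMSO, these were the largest rises and falls past the threshold whose arrays did not overlap between groups, which was not asked of the line difference. For the other contrasts they were the 3 largest rises and falls past the threshold. Genes of the NFAT pathway and its targets fixed beforehand were NFATC1, NFATC2, RCAN1, PPIA, MYC, JUN, EGR1, CCR7, IL10, IL6, IRF4, BCL2A1, MCL1, BCL2L1, CD83, CCL3 and CCL4. For each list spoken of, the 4 members with the smallest p were named. NFATC2 and CCL4 had mean values of 4.03 and 3.88, below the filter, and were not tested. XIST and Y-linked genes were left out of the named genes by a general rule.

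Alternatives chosen before the data were examined were median centring of each array, quantile normalization within each line, bead-level values as such or after background correction, no filter or a filter at the 70th percentile, all probes kept apart, fits with robust moderation and no trend, array weights, a replicate block, only the arrays compared, a minimum of 1.5-fold, a mean of all 4 times in HBL-1, camera on ranks, and each array left out in turn. Quantile normalization over all 27 arrays, the mean of all kept probes of a gene, means over 2 of the time points, and the line difference among genes above background on all DMSO arrays were added after the data had been seen.

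The limma fit and its threshold were tried on simulated values of the 12572 genes, of which 200 were changed. The noise was independent between genes, and the filter and the choice of probes were not simulated. At a log2 change of 0.5, the share recovered was 53% for HBL-1 at 12 h, 46% for HBL-1 at 48 h, 62% for the HBL-1 mean, 59% for HT at 12 h, 45% for HT at 36 h, 58% for the HT mean, 37% for the line difference, 43% for HT at 36 h against 12 h and 54% for the lines in DMSO. At a log2 change of 1, it was 95%, 84%, 99%, 95%, 94%, 96%, 82%, 90% and 90% in the same order. Tables were handled with data.table (version 1.17.8), numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15, probe matching used scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.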

Results

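Gene expression was measured on 27 Illumina HumanHT-12 arrays from HBL-1 and HT, cell lines of diffuse large B-cell lymphoma (DLBCL). HBL-1 is of the activated B-cell-like type, which depends on chronic B-cell receptor and NF-kB signalling, and HT is of the germinal centre B-cell-like type. The cells were treated with 600 nM cyclosporin A (CsA), which binds cyclophilin A and inhibits the phosphatase calcineurin, so that NFAT transcription factors stay out of the nucleus. HBL-1 had 5 groups, DMSO at 0 h and CsA for 12, 24, 36 and 48 h. HT had 4 groups, DMSO at 0 h and CsA for 12, 24 and 36 h. Each group had 3 arrays. No DMSO arrays of the later times were among the samples, so drug and time in culture changed together. The 48 h arrays lay on a BeadChip of their own, and all HT arrays lay on another.

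The mean of 12, 24 and 36 h against DMSO asks which genes changed under CsA in HBL-1. With DMSO at 0 h only, it cannot separate the drug from time in culture, and dependence on calcineurin was not tested. JUN, a subunit of AP-1 that acts together with NFAT, fell by 1.09 ± 0.125 (SE) on the log2 scale. SOCS3, a feedback inhibitor of cytokine signalling, fell by 1.63 ± 0.15, and IL4I1, an amino acid oxidase induced in activated B cells, fell by 1.15 ± 0.152. VPREB3, which associates with the immature B-cell receptor, rose by 1.63 ± 0.065. NLRP7, of the inflammasome family, rose by 1.70 ± 0.1. The other large rises were in FXYD6, NSG1, FAM43A, PVRIG, ATP9A, GNB3, PDCL3P4 and CACNA1H, with log2 fold changes of 1.11 to 1.39, and CACNA1H was above background on 1 of 3 DMSO arrays. The other large falls were in GPRC5C, DEPP1, GAS6, TYMP, GZMH, FMOD and CLDN23, with log2 fold changes of -1.86 to -0.96. For each of these genes all 9 CsA arrays lay beyond all 3 DMSO arrays, which was a condition for naming the largest changes. The other probe of SOCS3 gave 0.22, the other probe of GPRC5C -0.41 and that of PDCL3P4, a pseudogene, 0.25. The 3 other probes of TYMP gave -1.85 to -1.16.

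Among the NFAT pathway genes fixed beforehand, IRF4, the survival factor of this lymphoma type, was lower in HBL-1 (-0.35 ± 0.101, adjusted p = 0.0332), as was the activation marker CD83 (-0.33 ± 0.084, adjusted p = 0.0117). The CD83 fall rested on 12 h (-0.41) and 24 h (-0.46), as it was -0.12 at 36 h (limma adjusted p = 0.506). RCAN1, a calcineurin feedback gene, had -0.31 ± 0.127 (adjusted p = 0.176) and NFATC1 -0.23 ± 0.078 (adjusted p = 0.0855). BCL2A1, at -0.51 ± 0.166, was not past the threshold either (adjusted p = 0.0632). MYC (0.00), CCR7 (0.00), EGR1 (-0.06), BCL2L1 (-0.04), MCL1 (0.05), IL10 (-0.20), IL6 (-0.32), CCL3 (-0.28) and PPIA (0.23) were not past it. The other probe of IL10 gave -1.03, past the threshold where all probes were tested, so IL10 stays unsettled. At 36 h the other probe of BCL2L1 gave -0.58, past the threshold where all probes were tested, against -0.09 for the probe used. That of MCL1 gave -0.57 against 0.27, so BCL2L1 and MCL1 stay unsettled as well. The IRF4 call was lost without DMSO replicate 1 (adjusted p = 0.123), 2 (0.174) or 3 (0.08), CsA 12 h replicate 3 (0.0516), 24 h replicate 2 (0.0523) or 36 h replicate 2 (0.059), and the CD83 call without DMSO replicate 2 (0.0917). By limma, 660 of 12572 genes were past adjusted p 0.05, of which 422 rose and 238 fell. Without DMSO replicate 2 the count was 393 and without DMSO replicate 3 it was 377. With 12 and 24 h alone it was 376.

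Gene lists showed which programmes moved in HBL-1 over 12 to 36 h. NF-kB targets were lower, with 0 up and 7 down of 32 tested (camera adjusted p = 8.33e-08). NFKBIA, the inhibitor that NF-kB itself induces, fell by 0.67 ± 0.059, TNF fell by 0.88 ± 0.154 and NFKBIE fell by 0.44 ± 0.091. Calcium-NFAT-induced activation genes had 1 up and 4 down of 22 (camera adjusted p = 0.00044), where the phosphatase DUSP2 fell by 0.71 ± 0.113 and GEM by 0.75 ± 0.163. The antigen presentation genes of MHC class II went the other way, with 6 up and 0 down of 16 (camera adjusted p = 1.28e-10), led by HLA-DMB at 0.90 ± 0.08, CD74 at 0.46 ± 0.061, HLA-DMA at 0.42 ± 0.062 and HLA-DRA at 0.40 ± 0.075. Plasma cell genes had 8 up and 1 down of 22 (camera adjusted p = 0.000118), with TNFRSF17 at 0.73, MZB1 at 0.67, JCHAIN at 0.84 and SLAMF7 at 0.81. The germinal centre signature had 6 up and 0 down of 26 (camera adjusted p = 0.000564), with SERPINA9 at 0.84, ELL3 at 0.36 and STAP1 at 0.49 behind VPREB3. B-cell identity genes had 6 up and 1 down of 21 (camera adjusted p = 0.00423), with FCER2, the low-affinity IgE receptor, at 1.19 (above background on 2 of 3 DMSO arrays), BLK at 0.33, POU2AF1 at 0.21 and IKZF1 at -0.43. FOXO and quiescence genes had 6 up and 1 down of 24 (camera adjusted p = 0.00423), with the glucocorticoid-induced TSC22D3 at 0.86, TXNIP at 0.51, S1PR1 at 0.66 and CDKN2D at -0.34. Calls lost without DMSO replicate 1 were those of BLK (adjusted p = 0.0672) and GEM (0.0539), without replicate 2 those of POU2AF1 (0.0644) and STAP1 (0.193), and without replicate 3 those of POU2AF1 (0.144), STAP1 (0.101) and S1PR1 (0.0509).

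Proliferation genes were lower in the same contrast. DNA replication and S-phase genes had 0 up and 10 down of 46 (camera adjusted p = 1.95e-11), among them FEN1 at -0.31, TYMS at -0.27, MCM6 at -0.25 and POLE2 at -0.29. G2 and mitosis genes had 0 up and 4 down of 43 (camera adjusted p = 8.97e-07), namely CCNA2 at -0.29, CENPA at -0.31, CKAP2L at -0.27 and PLK1 at -0.31. MYC targets and ribosome biogenesis had 0 up and 6 down of 43 (camera adjusted p = 9.2e-07), with PPAN at -0.52, MRTO4 at -0.36, NOP56 at -0.22 and NIP7 at -0.23, while MYC itself did not change. Heat shock genes had 0 up and 3 down of 20 (camera adjusted p = 0.00215), namely FKBP4 at -0.26, STIP1 at -0.29 and HSPH1 at -0.22, and ER stress genes 3 up and 0 down of 27 (camera adjusted p = 0.000331), namely DNAJB9 at 0.41, XBP1 at 0.33 and DERL3 at 0.51. All 12 lists past camera in this contrast held with an estimated correlation, and fry gave adjusted p = 6.85e-07 for the NF-kB targets. Adjusted over the list alone, the counts up and down were 0 and 12 for NF-kB targets, 1 and 5 for calcium-NFAT genes, 10 and 0 for MHC class II, 10 and 2 for plasma cell genes, 6 and 0 for the germinal centre signature, 7 and 1 for B-cell identity, 8 and 2 for FOXO genes, 0 and 22 for DNA replication, 0 and 4 for mitosis, 0 and 10 for MYC targets, 1 and 7 for heat shock and 7 and 0 for ER stress. Calls lost without DMSO replicate 1 were those of POLE2 (adjusted p = 0.0796), CKAP2L (0.135), PLK1 (0.104), MRTO4 (0.0692), NOP56 (0.0614), NIP7 (0.0645), HSPH1 (0.419) and DERL3 (0.0751). Without DMSO replicate 2 the calls of TYMS (0.0754), CKAP2L (0.11), PLK1 (0.167), NOP56 (0.0811), NIP7 (0.112), STIP1 (0.0824) and XBP1 (0.0501) were lost. Without DMSO replicate 3 the calls of MCM6 (0.111), CKAP2L (0.0825), PLK1 (0.145), NOP56 (0.0988), NIP7 (0.116), FKBP4 (0.125), STIP1 (0.134), HSPH1 (0.0646) and DERL3 (0.0678) were lost. Among the CsA arrays, the PLK1 call was lost without 12 h replicate 2 (0.0645) or 3 (0.0556), 24 h replicate 1 (0.0598) or 3 (0.0749) or 36 h replicate 2 (0.0858). That of HSPH1 was lost without 12 h replicate 2 (0.0558) or 3 (0.0522), 24 h replicate 2 (0.0598) or 3 (0.072) or 36 h replicate 1 (0.0542) or 2 (0.0693), and that of CKAP2L without 24 h replicate 2 (0.0556) or 3 (0.0572) or 36 h replicate 1 (0.0513).

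The other 20 lists were not past camera for the HBL-1 mean. Chemokines, cytokines and receptors had 5 up and 1 down of 27 (adjusted p = 0.155), the AP-1 family 1 up and 3 down of 14 (0.247), B-cell receptor signalling 4 up and 1 down of 27 (0.247) and interferon-stimulated genes 3 up and 0 down of 31 (0.379). The activated B-cell-like signature had 2 up and 4 down of 30 (0.571), where STAT3 fell by 0.49 and BATF by 0.49, a BATF call lost without DMSO replicate 3 (0.0896). Amino acid and integrated stress response genes had 1 up and 1 down of 32 (0.687), NRF2 targets 1 up and 1 down of 19 (0.687), BCL2 family and apoptosis genes 1 up and 1 down of 26 (0.692), p53 targets 1 up and 0 down of 21 (0.712), hypoxia and glycolysis 2 up and 0 down of 32 (0.809) and cytosolic ribosomal proteins 0 up and 1 down of 48 (0.687). No member was past the threshold among histone genes (0.247), oxidative phosphorylation (0.453), calcineurin-NFAT pathway components (0.692), cholesterol biosynthesis (0.93) and MHC class I (0.93). The markers of other cell types were not past it in either direction, whether epithelial (0.389), T-cell (0.454), stromal (0.853) or myeloid (0.853). Median, mean and camera direction differed in sign for the AP-1 family, oxidative phosphorylation, the activated B-cell-like signature, the integrated stress response, calcineurin-NFAT components, p53 targets and MHC class I.

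**Figure D1:**
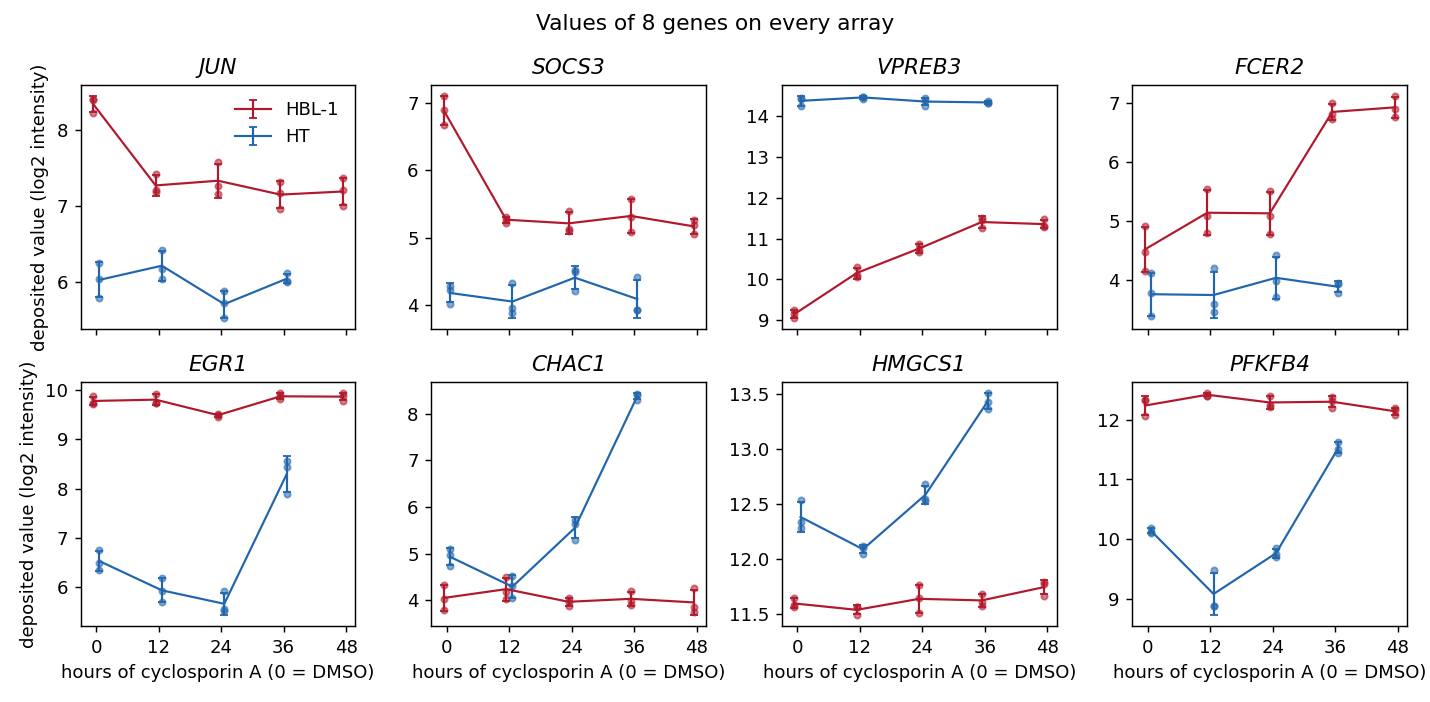
Deposited log2 intensity of 8 genes on every array against hours of CsA (0 is DMSO), HBL-1 in red and HT in blue; points are arrays and lines join group means with error bars of 1 SD over 3 arrays. JUN and SOCS3 were lower at every CsA time point in HBL-1, and EGR1, CHAC1 and PFKFB4 were higher at 36 h than at 12 h in HT.

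The single time points of HBL-1 ask in which order these genes moved. The NF-kB and calcium-NFAT lists were past camera downwards at 12 h, while the MHC class II and mitosis lists were first past it at 24 h. At 12 h JUN fell by 1.07 ± 0.153, TNF by 1.11 ± 0.189, DUSP2 by 0.89 ± 0.139 and NFKBIA by 0.61 ± 0.072. NF-kB targets had 0 up and 4 down of 32 (camera adjusted p = 4.4e-08; 0 and 10 adjusted over the list alone) and calcium-NFAT genes 0 up and 3 down of 22 (camera adjusted p = 6.83e-06; 1 and 6 adjusted over the list alone). MHC class II genes had 2 up and 0 down of 16 at 12 h (camera adjusted p = 0.127; 2 and 0 adjusted over the list alone), with HLA-DMB already higher by 0.60, and mitosis genes 0 up and 0 down of 43 (0.534). At 24 h MHC class II had 3 up and 0 down of 16 (camera adjusted p = 2.67e-05; 4 and 0 adjusted over the list alone), with HLA-DMB at 0.76. Mitosis genes had 0 up and 1 down of 43 (camera adjusted p = 3.26e-08) and 0 and 4 adjusted over the list alone. NF-kB targets had 0 up and 6 down of 32 at 24 h (camera adjusted p = 3.39e-11; 0 and 12 adjusted over the list alone) and calcium-NFAT genes 0 up and 2 down of 22 (0.000134; 0 and 7). The largest rises at 12 h were in NLRP7 (1.30), GUCY2C (1.12) and FXYD6 (1.07), and the largest falls in GPRC5C (-1.86), SOCS3 (-1.63, other probe 0.33) and DEPP1 (-1.23). NFATC1 was lower at 12 h (-0.36 ± 0.095, adjusted p = 0.0354), with other probes from -0.61 to 0.18, and the call was lost without DMSO replicate 2 (0.221) or 3 (0.188) or without CsA 12 h replicate 1 (0.0838) or 2 (0.11). At 24 h the largest rises were in NLRP7 (1.74), VPREB3 (1.61) and FXYD6 (1.52), and the largest falls in SOCS3 (-1.68), GPRC5C (-1.65) and DEPP1 (-1.63).

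At 36 h in HBL-1 FCER2 rose by 2.33 ± 0.233, VPREB3 by 2.26 ± 0.08 and NSG1 by 2.06 ± 0.17, while GPRC5C (-2.05), DEPP1 (-1.80) and SOCS3 (-1.57) fell. MHC class II genes had 11 up and 0 down of 16 (camera adjusted p = 2.94e-17; 13 and 0 adjusted over the list alone), with HLA-DMB at 1.35 and CD74 at 0.76. Mitosis genes had 0 up and 17 down of 43 (camera adjusted p = 2.1e-11; 0 and 23 adjusted over the list alone), with CENPA at -0.59 and PLK1 at -0.65. Plasma cell genes had 9 up and 0 down of 22 (camera adjusted p = 2.58e-06; 13 and 2 adjusted over the list alone), where JCHAIN rose by 1.56. ER stress genes had 12 up and 0 down of 27 (camera adjusted p = 5.42e-08; 15 and 0 adjusted over the list alone). The NF-kB targets had 0 up and 5 down of 32 at 36 h (camera adjusted p = 0.0467, and adjusted p = 0.0717 with an estimated correlation), a call lost without DMSO replicate 2 (0.0828) or 3 (0.0548) or CsA 36 h replicate 3 (0.0918). Calcium-NFAT genes were not past camera at 36 h, with 1 up and 2 down of 22 (0.38; 2 and 4 adjusted over the list alone). Between 12 h and 36 h of CsA, a comparison without DMSO arrays, MHC class II rose (12 up and 0 down of 16, camera adjusted p = 2.29e-16) and mitosis genes fell (0 up and 22 down of 43, camera adjusted p = 1.93e-15). Both lists held with an estimated correlation. Without 36 h replicate 2 the mitosis calls of CENPE (limma adjusted p = 0.129) and NUSAP1 (0.096) were among those lost. Calcium-NFAT genes had 4 up and 0 down of 22 from 12 h to 36 h (camera adjusted p = 0.0262, and adjusted p = 0.0563 with an estimated correlation), a call lost without 12 h replicate 2 (0.0753). TNF, DUSP2, NFATC1 and LTA rose from 12 h to 36 h, by 0.65, 0.50, 0.36 and 0.50, and the other probes of NFATC1 gave -0.44 to 0.52. The TNF call was lost without 12 h replicate 1 (adjusted p = 0.0621) or 3 (0.0665) or 36 h replicate 1 (0.0569) or 2 (0.128). That of DUSP2 was lost without 12 h replicate 1 (0.0908) or 36 h replicate 1 (0.0846) or 2 (0.105), and that of NFATC1 without 12 h replicate 2 (0.0585) or 36 h replicate 1 (0.087). The largest changes in that comparison were in FCER2 (1.71), SNORD3C (1.476), NEU4 (1.39), EIF3CL (-1.34), AFMID (-1.28, other probe 0.03) and POM121 (-1.25).

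By limma 213 genes were past the threshold at 12 h in HBL-1 (143 up and 70 down), 309 at 24 h (205 up and 104 down), 1587 at 36 h (855 up and 732 down) and 1358 between 12 h and 36 h (615 up and 743 down). The 12 h count was 85 without DMSO replicate 2, 88 without DMSO replicate 3, 91 without CsA replicate 1 and 423 without CsA replicate 2. It was 48 with only the arrays compared in the fit. CsA 12 h replicate 1 lay apart from the other HBL-1 arrays, at -26.15 on principal component 2, where the others ran from -5.06 to 12.45. Its deviation from the group mean had the largest SD of all arrays (0.198). The 24 h count was 187 without DMSO replicate 2, 192 without CsA replicate 2 and 204 without CsA replicate 3. The 36 h count was 768 without CsA 36 h replicate 2. The count between 12 h and 36 h was 485 without 36 h replicate 2 and 804 without 12 h replicate 1.

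**Figure D2:**
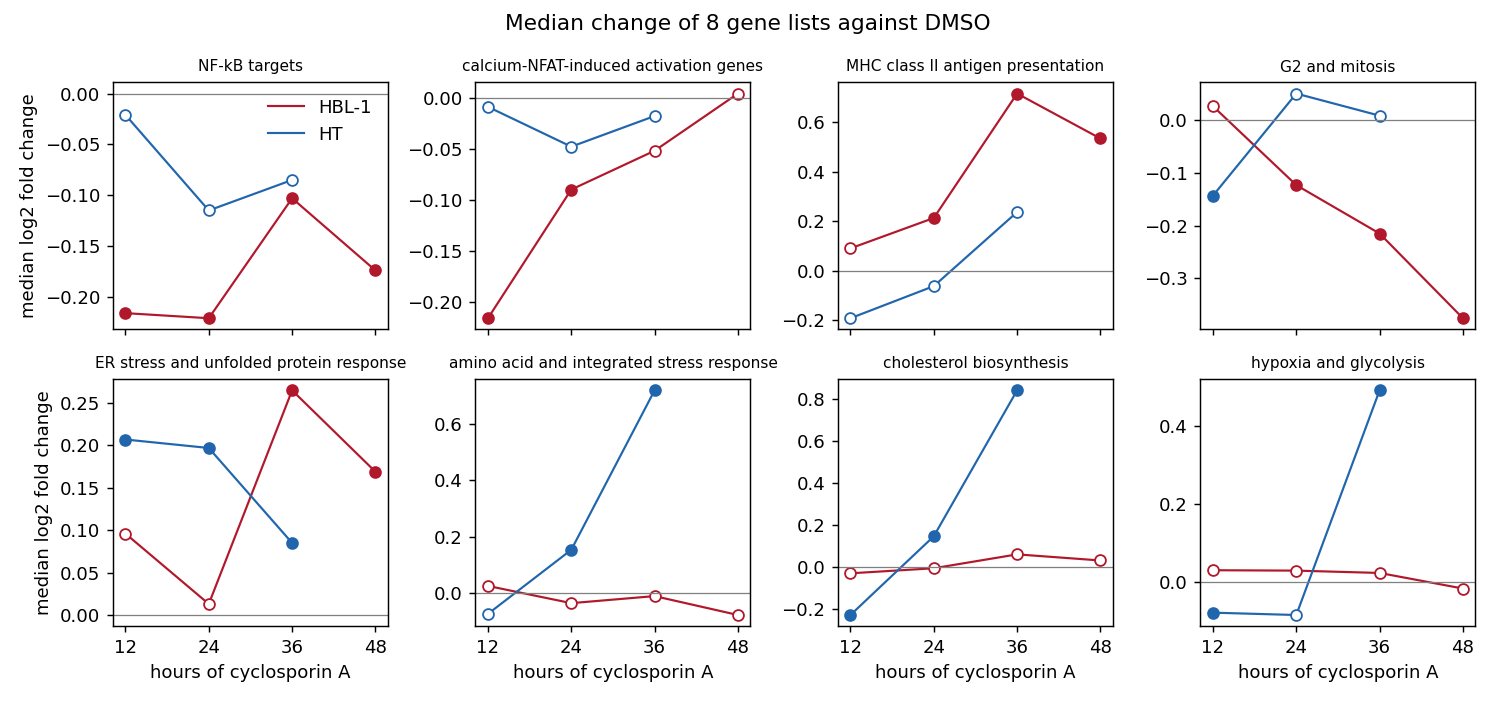
Median log2 fold change against DMSO of the tested members of 8 gene lists at each CsA time point in hours, HBL-1 in red and HT in blue; filled points are past camera adjusted p 0.05 and open points are not. MHC class II in HBL-1 reached 0.72 and the integrated stress response in HT 0.72, both at 36 h.

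The 48 h arrays extend the course in HBL-1. FCER2 rose by 2.41 ± 0.233, NSG1 by 2.39 ± 0.17, NLRP7 by 2.30 ± 0.122 and VPREB3 by 2.21 ± 0.08. CACNA1H, FAM43A, CUEDC1, PDCL3P4 and FXYD6 rose by 1.67 to 1.80, and MMP11, whose DMSO values lay in the background, was at least 2.58-fold higher. GPRC5C, DEPP1, SOCS3 (other probe 0.15), GZMH, GAS6, IL4I1, LAG3, GEM, VSNL1 and GTF2A1 fell, with log2 fold changes of -1.81 to -1.38. VSNL1 was above background on 1 of 3 arrays at 48 h and CACNA1H on 1 of 3 DMSO arrays. JUN fell by 1.15 ± 0.153. All 3 arrays at 48 h lay beyond all 3 DMSO arrays for the genes of the largest changes, as the naming rule required. PPIA, which encodes the protein that CsA binds, was lower (-0.62 ± 0.204, adjusted p = 0.0401), a call lost without CsA 48 h replicate 1 (0.18) or 2 (0.0798) or without DMSO replicate 1 (0.102), 2 (0.0677) or 3 (0.108). The PPIA probe was dim, with a DMSO mean of 5.38 against a background ceiling of 4.33, and no other probe of PPIA was kept. RCAN1 (-0.32), IRF4 (-0.35, adjusted p = 0.0607), NFATC1 (-0.20), BCL2A1 (-0.45), CD83 (0.04), MYC (0.16), EGR1 (0.09), CCR7 (0.14), BCL2L1 (-0.17), MCL1 (-0.04), IL6 (0.09), IL10 (0.00, other probe -1.20) and CCL3 (-0.01) were not past the threshold.

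At 48 h G2 and mitosis genes had 0 up and 34 down of 43 (camera adjusted p = 1.29e-25; 0 and 36 adjusted over the list alone), with CCNA2 at -0.47, CDK1 at -0.51, CKAP2L at -0.59 and CENPA at -0.52. DNA replication genes had 0 up and 20 down of 46 (camera adjusted p = 9.05e-12; 0 and 28 adjusted over the list alone), with TK1 at -0.59 and RFC2 at -0.61. MHC class II had 10 up and 0 down of 16 (camera adjusted p = 7.44e-16; 12 and 0 adjusted over the list alone), with HLA-DMB at 1.36 and HLA-DMA at 0.91. Plasma cell genes had 8 up and 2 down of 22 (camera adjusted p = 0.000387), with JCHAIN at 1.51 and SLAMF7 at 1.11, the germinal centre signature 7 up and 1 down of 26 (0.000121), B-cell identity 6 up and 2 down of 21 (0.00108) and ER stress 8 up and 0 down of 27 (5.1e-05). Chemokines, cytokines and receptors had 6 up and 1 down of 27 (camera adjusted p = 0.00224), where LTB rose by 1.61, TNFRSF17 by 1.09, TNFRSF13C by 0.79 and IL16 by 0.85. NF-kB targets had 1 up and 5 down of 32 (camera adjusted p = 0.00683), with NFKBIA at -0.64 and BCL3 at -0.55. B-cell receptor signalling had 7 up and 0 down of 27 (camera adjusted p = 0.0164), with FCGR2B at 0.66 and CD22 at 0.47, and was lost without CsA 48 h replicate 3 (0.0509). Heat shock genes had 0 up and 5 down of 20 (camera adjusted p = 0.00683, and adjusted p = 0.0713 with an estimated correlation). Calcium-NFAT genes were not past camera (0.67), with a median of 0.00 and a mean of -0.09, although GEM fell by 1.44. Adjusted over the list alone, the counts up and down were 11 and 3 for plasma cell genes, 9 and 1 for the germinal centre signature, 6 and 2 for B-cell identity, 9 and 0 for ER stress, 7 and 3 for cytokines, 1 and 9 for NF-kB targets, 8 and 1 for B-cell receptor signalling and 1 and 9 for heat shock. In total 1493 genes were past the threshold, 742 up and 751 down. The count was 953 without DMSO replicate 1 and 968 without CsA 48 h replicate 1. The chip of the 48 h arrays and the time cannot be told apart from these arrays alone.

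**Figure D3:**
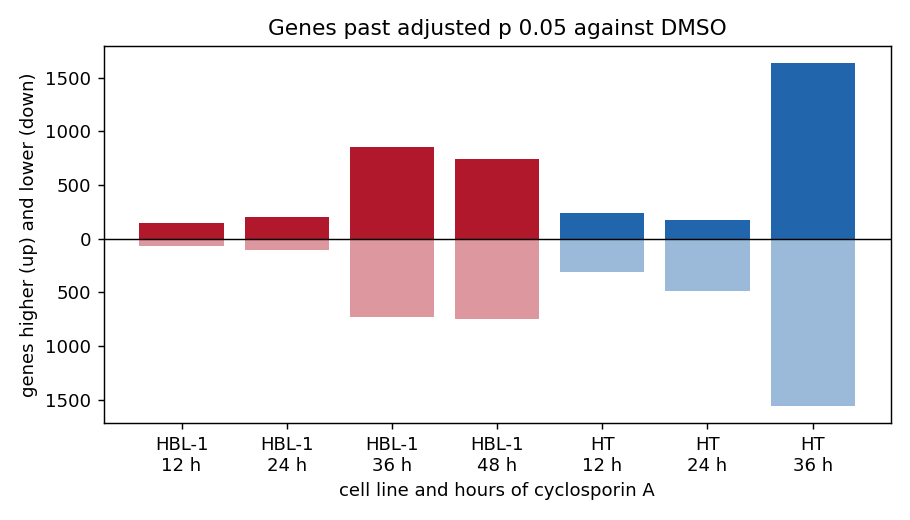
Number of genes past limma adjusted p 0.05 against DMSO at each CsA time point, rises above 0 and falls below 0, HBL-1 in red and HT in blue. HT at 36 h had 1636 rises and 1558 falls and HBL-1 at 12 h had 143 and 70.

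The same comparisons in HT ask whether a line without chronic NF-kB activity responds in the same way. Stress and lipid synthesis genes changed in HT. At 12 h the redox genes SQSTM1 (0.63 ± 0.068), HMOX1 (0.90 ± 0.104) and SLC7A11 (1.02 ± 0.176) rose, and NRF2 targets had 5 up and 0 down of 19 (camera adjusted p = 1.82e-05; 5 and 0 adjusted over the list alone). The glycolysis regulator PFKFB4 fell by 1.05 ± 0.101, BNIP3 by 0.67 and ANKRD37 by 0.71, while ALDOC rose by 0.44. Hypoxia and glycolysis genes had 1 up and 10 down of 32 (camera adjusted p = 1.82e-05, and adjusted p = 0.0779 with an estimated correlation). Cholesterol biosynthesis genes had 0 up and 6 down of 21 (camera adjusted p = 4.34e-05; 0 and 10 adjusted over the list alone), with INSIG1 at -0.53, FDPS at -0.40, MSMO1 at -0.45 and HMGCS1 at -0.29. The MSMO1 call was lost without DMSO replicate 1 (adjusted p = 0.0627) or 3 (0.0625) or CsA 12 h replicate 2 (0.0916), and that of HMGCS1 without DMSO replicate 3 (0.13) or CsA 12 h replicate 2 (0.0581). The calls of MVK and SQLE were lost without DMSO replicate 1 (0.128 and 0.18) or 3 (0.083 and 0.166). They were also lost without CsA 12 h replicate 2 (0.1 and 0.0893) or 3 (0.12 and 0.209). Without DMSO replicate 3 the fold changes of MVK and SQLE were still -0.43 and -0.24. Most of the 6 calls thus lay close to the threshold and did not rest on DMSO replicate 3 alone. ER stress genes had 3 up and 0 down of 27 (camera adjusted p = 7.23e-07) and mitosis genes 0 up and 5 down of 43 (4.09e-05). The mitosis calls of AURKB (limma adjusted p = 0.178), HJURP (0.116), CDC25C (0.0824) and CENPA (0.0507) were lost without DMSO replicate 3. The largest changes at 12 h were in COL9A2 (1.69), MYBPHL (1.68), EVI2B (1.35), KIDINS220 (-1.07), PFKFB4 and OLMALINC (-1.05). COL9A2 was above background on 1 of 3 DMSO arrays and KIDINS220 on 2 of 3 arrays at 12 h. NFATC1 fell by 0.58 ± 0.095 at 12 h in HT (adjusted p = 0.000172), while its 3 other probes, from -0.58 to -0.02, were not past the threshold. It was -0.20 at 24 h and 0.12 at 36 h, neither past the threshold, and rose by 0.70 from 12 h to 36 h (adjusted p = 2.8e-07, other probes -0.15 to 0.94). CHAC1, of the integrated stress list and above background on 1 of 3 arrays at 12 h, fell by 0.64 ± 0.189 (adjusted p = 0.0435), a call lost without DMSO replicate 1 (0.158) or 3 (0.121) or CsA 12 h replicate 1 (0.19) or 3 (0.0982). TRIB3 (-0.42), ATF3 (-0.61), PMAIP1 (-0.62) and CEBPB (-0.37) fell too at 12 h, while SLC7A5 (0.29) and SLC3A2 (0.29) rose. Each of these calls was lost without DMSO replicate 3. Other single arrays mattered too, for ATF3 DMSO replicate 2 (0.124), for SLC3A2 and SLC7A5 DMSO replicate 1 (0.117 and 0.0502) and for PMAIP1 CsA 12 h replicate 3 (0.114). ATF3 was above background on 0 of 3 arrays at 12 h and 2 of 3 in DMSO, so the size of its fall is uncertain. EGR1 fell by 0.60 ± 0.137 at 12 h, a call lost without DMSO replicate 3 (0.0739) or CsA 12 h replicate 3 (0.0727).

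At 36 h RNA of integrated stress response genes was higher in HT than in DMSO at 0 h, where drug and time in culture cannot be told apart. CHAC1 rose by 3.45 ± 0.189, DDIT3 by 2.59 ± 0.123, PCK2 by 2.10 ± 0.107, PSAT1 by 1.98 ± 0.08 and ASNS by 1.476 ± 0.071. Amino acid and integrated stress genes had 26 up and 1 down of 32 (camera adjusted p = 2.62e-29; 26 and 1 adjusted over the list alone). Hypoxia and glycolysis genes, lower at 12 h, had 24 up and 0 down of 32 (camera adjusted p = 6.55e-24; 25 and 0 adjusted over the list alone), with ALDOC at 1.91, HILPDA at 1.42, SLC2A3 at 1.35 and PFKFB4 at 1.39. Cholesterol genes had 17 up and 0 down of 21 (camera adjusted p = 8.6e-22; 17 and 2 adjusted over the list alone), with ACAT2 at 1.22, HMGCS1 at 1.05, MVD at 1.54 and EBP at 1.29. MYC targets had 1 up and 27 down of 43 (camera adjusted p = 1.19e-10; 1 and 29 adjusted over the list alone), where NOP2 fell by 0.57 and RRS1 by 0.66, and MYC itself fell by 0.37 ± 0.09. Heat shock genes had 0 up and 13 down of 20 (camera adjusted p = 5.74e-09; 0 and 14 adjusted over the list alone), with HSPA1A at -1.30 and HSPA1B at -1.31. These 5 lists held with an estimated correlation. ER stress genes had 9 up and 4 down of 27 at 36 h (camera adjusted p = 0.0416; 9 and 4 adjusted over the list alone), and adjusted p = 0.253 with an estimated correlation. That call was also lost without DMSO replicate 1 (0.0677) or CsA 36 h replicate 1 (0.0853). EGR1 rose by 1.77 ± 0.137 at 36 h and RCAN1 fell by 1.19 ± 0.156. CD83 was also lower at 36 h in HT (-0.28 ± 0.102, limma adjusted p = 0.0386, other probe -0.08). CFAP96 (2.70) was among the largest rises and DDX6 (-1.51), RGL4 (-1.49) and WIPI2 (-1.31) were the largest falls. From 12 h to 36 h PFKFB4 rose by 2.45, HMGCS1 by 1.35, CHAC1 by 4.09, SYTL1 by 2.81 and EGR1 by 2.37, and CFAP96 was at least 9.84-fold higher. CHAC1 and SYTL1 were each above background on 1 of 3 arrays at 12 h, so their sizes are uncertain. MYBPH (-2.10), NUP98 (-1.84), DUSP5 (-1.71) and RCAN1 (-1.35) fell between these times.

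At 24 h in HT ER stress genes were higher, with 9 up and 1 down of 27 (camera adjusted p = 1.26e-12), led by DNAJB9 at 0.65 and SDF2L1 at 0.49. The integrated stress list had 6 up and 1 down of 32 (camera adjusted p = 2.71e-07), with PSAT1 at 0.65 and ASNS at 0.41, and cholesterol genes 4 up and 0 down of 21 (camera adjusted p = 0.000102, and adjusted p = 0.0569 with an estimated correlation). The counts of members depended on single arrays. Calls of list genes lost without DMSO replicate 2 included HSPA5 (limma adjusted p = 0.107), DNAJB11 (0.0871), DDIT3 (0.0711), CHAC1 (0.189) and MSMO1 (0.302). That of ACAT2 was lost without DMSO replicate 3 (0.0807). EGR1 fell by 0.87 ± 0.137. INHBE rose by 0.85, KLF3 was at least 1.54-fold higher, and DEAF1 (-1.09), SPEF2 (-1.01) and CHMP6 (-0.997) fell, the last 2 above background on 1 of 3 arrays at 24 h. The KLF3 call was lost without DMSO replicate 1 (adjusted p = 0.0716) or 2 (0.111) or CsA 24 h replicate 3 (0.29), and the INHBE call without DMSO replicate 2 (0.0953). The number of genes called at 24 h depended on the scaling of the arrays. As deposited, 175 rose and 484 fell, after quantile normalization within the line 125 rose and 85 fell, and after median centring 106 rose and 930 fell. The median of all genes was -0.07 as deposited, -0.12 after centring and -0.02 after quantile normalization. The 24 h count of 659 was 217 without DMSO replicate 2, 391 without DMSO replicate 1, 233 without CsA 24 h replicate 2 and 373 without CsA 24 h replicate 3. By limma 549 genes were past the threshold at 12 h (242 up and 307 down), 3194 at 36 h (1636 up and 1558 down) and 3788 between 12 h and 36 h (1968 up and 1820 down). The 12 h count was 290 without DMSO replicate 1, 292 without DMSO replicate 3, 359 without CsA 12 h replicate 2 and 334 without CsA 12 h replicate 3.

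Averaged over 12, 24 and 36 h, HT had higher ER stress and integrated stress genes and lower heat shock genes. EVI2B rose by 0.95 ± 0.1, the stress transcription factor ATF5 by 0.56 ± 0.057 and the ER chaperone DNAJB9 by 0.55 ± 0.077. LNPK, MYDGF, H2AC6 and BET1 rose by 0.54 to 0.68, and APOC1 and SYT2, at background in DMSO, were at least 1.3-fold and 1.31-fold higher. SGPP2 rose too, with 0 of 3 DMSO arrays above background and a CsA mean below its ceiling, so no fold is given. PRR19, SPEF2, KIDINS220, MIR1253, PRR15L, TAMALIN, OPA3, BIK, MMP23B (other probe 0.23) and RAB34 fell, with log2 fold changes of -0.97 to -0.71. SPEF2 was above background on 2 of 3 arrays at 12 h and 1 of 3 at 24 h. KIDINS220 was above it on 2 of 3 at 12 h and at 36 h, and RAB34 on 1 of 3 at 12 h and at 24 h. All 9 CsA arrays lay beyond all 3 DMSO arrays for the genes of the largest rises and falls, as the naming rule required. The RCAN1 mean was -0.46 ± 0.127 (adjusted p = 0.0231), a call lost without DMSO replicate 1 (0.113) or 3 (0.111). It rested on 36 h, since RCAN1 was 0.16 at 12 h (adjusted p = 0.652) and -0.36 at 24 h (adjusted p = 0.177). The other genes fixed beforehand were not past the threshold, namely MYC (-0.11), JUN (-0.04), EGR1 (0.10), NFATC1 (-0.22), IRF4 (0.09), CD83 (-0.14), BCL2A1 (-0.36), BCL2L1 (-0.12), MCL1 (-0.07), IL10 (0.09) and PPIA (-0.02). The mean hides changes at single times. MCL1 fell by 0.40 from 12 h to 36 h (limma adjusted p = 0.00192, other probe -1.15). At 36 h against DMSO it was -0.23 (adjusted p = 0.0994), while its other probe, at -0.70, was past the threshold. BCL2L1 fell by 0.35 at 24 h (adjusted p = 0.0414), a call lost without DMSO replicate 1 (0.163) or 3 (0.145) or CsA 24 h replicate 2 (0.11) or 3 (0.17). CCR7 was above background on 0 of 3 arrays in every HT group, IL6 on 1 of 3 in DMSO and CCL3 on 1 of 3 in DMSO, so a fall of these 3 genes in HT could not be measured. Without DMSO replicate 2, the calls of SYT2 (0.133), APOC1 (0.0567), SGPP2 (0.0527) and RAB34 (0.062) were lost, and without DMSO replicate 1 those of SYT2 (0.0679), SGPP2 (0.0549) and H2AC6 (0.0542). In total 807 genes were past the threshold, 355 up and 452 down. The count was 397 without DMSO replicate 1, 310 without DMSO replicate 2, 506 without DMSO replicate 3 and 322 with 12 and 24 h alone.

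The HT mean had 18 up and 0 down of 32 integrated stress genes (camera adjusted p = 4.12e-24; 23 and 1 adjusted over the list alone), 8 up and 0 down of 27 ER stress genes (2.13e-10; 13 and 0) and 0 up and 8 down of 20 heat shock genes (3.29e-07; 0 and 12). Cholesterol genes had 10 up and 0 down of 21 (camera adjusted p = 2.37e-12; 14 and 1 adjusted over the list alone) and hypoxia genes 5 up and 0 down of 32 (1.09e-06; 5 and 0). With 12 and 24 h alone the median of the cholesterol list was -0.055 (adjusted p = 0.951) and that of the hypoxia list -0.10 (adjusted p = 0.00173), so the rise of both rested on 36 h. The heat shock list then had a median of -0.104 (adjusted p = 0.108) and the MYC targets -0.023 (adjusted p = 0.905), and neither was past camera. MYC targets had 1 up and 5 down of 43 (camera adjusted p = 4.95e-05). DNA replication had 0 up and 6 down of 46 (camera adjusted p = 0.00493, and adjusted p = 0.0615 with an estimated correlation) and p53 targets 3 up and 1 down of 21 (camera adjusted p = 0.0241, and adjusted p = 0.052 with an estimated correlation). The p53 call was also lost without DMSO replicate 2 (adjusted p = 0.0754). NF-kB targets (2 up and 2 down of 32, 0.513), calcium-NFAT genes (1 up and 1 down of 22, 0.909) and MHC class II (1 up and 0 down of 16, 0.964) were not past camera in HT. Some activation genes were already at background there. TNFAIP3, CCL22, EBI3, CD69 and GEM were above it on 0 of 3 HT DMSO arrays and ICAM1 on 1 of 3. A fall of these genes could not be measured in HT, so the list results do not show an absent response.

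The difference between the lines in the 12 to 36 h response was tested itself. JUN and NFKBIA had lower changes in HBL-1 than in HT, and VPREB3, ATP9A and LTB had higher ones. LTB rose by 0.999 in HBL-1 and fell by 0.465 in HT, a fall lost without HT DMSO replicate 1 (adjusted p = 0.0889). NLRP7 differed by 1.92 ± 0.141, VPREB3 by 1.62 ± 0.092 and LTB, which encodes lymphotoxin beta, by 1.47 ± 0.155. NSG1, ATP9A, P3H3, FXYD6, SLC43A2, TMEM132A and SUSD3 differed by 1.23 to 1.54. JUN differed by -1.06 ± 0.177, GPRC5C by -1.91, SOCS3 by -1.63 (other probe 0.32), and DEPP1, GAS6, SPNS3, BSPRY, LYSMD2, CHAC1, IL4I1 and CCL3L3 by -1.35 to -1.08. In HT, NLRP7 was above background on 1 of 3 DMSO arrays, and NSG1, FXYD6, GPRC5C, SOCS3, DEPP1, GAS6, SPNS3, BSPRY, LYSMD2, IL4I1 and CCL3L3 on 0 of 3. In HBL-1, CHAC1 was above it on 0 of 3 and SPNS3 on 1 of 3. A fall of these genes could not be measured in that line, so their differences mostly show the change in the other line. Among the 9416 genes above background on all DMSO arrays of both lines, 470 differed. The CCL3L3 call was lost without HBL-1 DMSO replicate 3 (adjusted p = 0.0753). The differences of MYC (0.11), EGR1 (-0.16), IRF4 (-0.44, adjusted p = 0.0745), RCAN1 (0.15), NFATC1 (0.00), CD83 (-0.19), BCL2A1 (-0.15), BCL2L1 (0.08), MCL1 (0.12), IL10 (-0.28, other probe -1.24) and PPIA (0.25) were not past the threshold. By limma 522 genes differed, 333 with the higher change in HBL-1 and 189 with the higher change in HT. CCR7, IL6 and CCL3 could not be compared, as they were near background in HT. The count was 287 without HBL-1 DMSO replicate 1, 317 without HT DMSO replicate 2 and 246 with 12 and 24 h alone, where CHAC1 (0.065) and SPNS3 (-0.404) were not past the threshold.

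Among the lists, the integrated stress response (0 up and 13 down of 32, camera adjusted p = 5.71e-18; 0 and 17 adjusted over the list alone) and cholesterol biosynthesis (0 up and 6 down of 21, 6.52e-08; 0 and 10) were higher in the HT response, with PSAT1 at -0.94 and ACAT2 at -0.61. MHC class II (6 up and 0 down of 16, 6.35e-07; 10 and 0), B-cell identity (5 up and 0 down of 21, 0.00305; 5 and 0) and the germinal centre signature (3 up and 0 down of 26, 0.00363; 5 and 1) were higher in the HBL-1 response, with HLA-DMB at 0.81, POU2AF1 at 0.38 and SERPINA9 at 0.91. NF-kB targets had 0 up and 3 down of 32 (camera adjusted p = 0.0014; 0 and 5 adjusted over the list alone), with NFKBIA at -0.57. Among genes above background on all DMSO arrays, their median was -0.038 (camera adjusted p = 0.0355). Calcium-NFAT genes had 0 up and 2 down of 22 (camera adjusted p = 0.0154; 0 and 3 adjusted over the list alone), and were lost without HT DMSO replicate 3 (0.0745). That call was also lost among genes above background on all DMSO arrays, with a median of -0.005 (adjusted p = 0.149), so a line difference of this list is not established. Mitosis genes had 0 up and 0 down of 43 (camera adjusted p = 0.0115). Hypoxia genes (0 up and 3 down of 32) had camera adjusted p = 0.0014, and adjusted p = 0.15 with an estimated correlation. DNA replication (1 up and 1 down of 46) had camera adjusted p = 0.0129, and adjusted p = 0.101 with an estimated correlation. The other 8 of the 10 lists past camera held with an estimated correlation. With 12 and 24 h alone, the medians of the integrated stress response (-0.04, adjusted p = 0.0717), cholesterol biosynthesis (0.039, 0.817), B-cell identity (0.081, 0.414) and mitosis (-0.001, 0.496) were not past camera. The hypoxia list turned to 0.091 (adjusted p = 0.011). These differences therefore rested on 36 h, as did those of PSAT1 (-0.283, adjusted p = 0.134) and ACAT2 (-0.203, adjusted p = 0.201). NF-kB targets (-0.207, adjusted p = 2.03e-05) and MHC class II (0.405, adjusted p = 0.000868) stayed past camera without it.

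Genes past the threshold in both lines overlapped in the same direction more than independent genes would. Fisher's test treats genes as independent, which they are not, so its p-values are descriptive only. Time in culture was common to both lines and cannot be told apart from the drug here. DNAJB9, TNFRSF17, DDIT3 and ALOX5AP were among 43 genes that rose in both 12 to 36 h means, where 11.9 were expected (Fisher's exact test, two-sided, adjusted p = 8.08e-13 over 4 overlaps). NFKBIE was among 19 that fell in both, where 8.6 were expected (adjusted p = 0.00226). IL10RA and SIGLEC10 were among 22 that rose in HBL-1 and fell in HT, where 15.2 were expected (adjusted p = 0.109), and SRGN and WARS1 were among 5 of the reverse pattern, where 6.7 were expected (adjusted p = 0.691). The 43 became 28 and 27 without HBL-1 DMSO replicates 2 and 3 and 20, 21 and 25 without HT DMSO replicates 1, 2 and 3. The 19 became 8, 5 and 12 without HBL-1 DMSO replicates 2 and 3 and CsA 36 h replicate 2, 12, 10 and 12 without HT DMSO replicates 1, 2 and 3, and 29 without HT CsA 24 h replicate 1. The 22 became 12 and 14 without HBL-1 DMSO replicates 1 and 2, and 9, 8 and 13 without HT DMSO replicates 1, 2 and 3. The 5 became 8 without HBL-1 CsA 12 h replicate 2, and 3, 2 and 3 without HT DMSO replicates 1, 2 and 3. Across the 12572 genes, which are not independent replicates, Pearson's r between the mean responses was 0.086 and Spearman's rho 0.097.

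In DMSO, genes of activated B cells were higher in HBL-1 and several genes of germinal centre B cells were higher in HT. CCND2 and CD44 were at least 777-fold and 518-fold higher in HBL-1, and the chemokine receptor CCR7 was at least 219-fold higher. IRF4 was higher by 5.55 ± 0.124, CD83 by 4.23, EGR1 by 3.26, JUN by 2.32, IL6 by 2.07 (above background on 1 of 3 HT arrays), IL10 by 1.90, BCL2L1 by 0.96 and RCAN1 by 0.80. CDH2, IL17RB, PHGDH (above background on 2 of 3 HT arrays), CT45A3 (1 of 3), YBX3, RCAN2, TENT5C and MARCKS were also among the genes highest in HBL-1. OSBPL1A and CD27 were at least 263-fold and 116-fold higher in HT, SERPINA9 differed by -7.25 ± 0.103, and CAPN13, C11orf97, ACTL8, EFR3B and DEPTOR were among the genes highest in HT. C11orf97 and ACTL8 were each above background on 1 of 3 HBL-1 arrays. PPIA (-1.96), MCL1 (-0.91) and MYC (-0.22, other probe 0.12) were lower in HBL-1, while NFATC1 (-0.14) and CCL3 (0.39) were not past the threshold. The PPIA probe had means of 5.38 in HBL-1 and 7.33 in HT, and no other probe of PPIA was kept. BCL2A1 was higher by 0.45 ± 0.203 (adjusted p = 0.0464), a call lost without HBL-1 DMSO replicate 1 (0.142) or 3 (0.161) or HT DMSO replicate 2 (0.182) or 3 (0.0691). The MYC call was lost without HBL-1 DMSO replicate 1 (0.0883) or 2 (0.0714) or HT DMSO replicate 1 (0.189). The activated B-cell-like signature had 27 up and 0 down of 30 (camera adjusted p = 9.5e-17), NF-kB targets 27 up and 2 down of 32 (1.04e-12), chemokines and cytokines 20 up and 3 down of 27 (6.48e-08), calcium-NFAT genes 15 up and 2 down of 22 (4.62e-06), B-cell receptor signalling 18 up and 4 down of 27 (0.000269) and the germinal centre signature 5 up and 19 down of 26 (4.62e-06). These 6 lists held with an estimated correlation. Hypoxia genes (22 up and 3 down of 32, 4.47e-05) and heat shock genes (3 up and 15 down of 20, 0.00771) both had adjusted p = 0.0879 with an estimated correlation. Oxidative phosphorylation (3 up and 27 down of 40, 0.00376) had adjusted p = 0.136 and mitosis (6 up and 28 down of 43, 0.0129) adjusted p = 0.0649 with an estimated correlation. Adjusted over the list alone, the counts up and down were 27 and 0 for the activated B-cell-like signature, 28 and 2 for NF-kB targets, 16 and 2 for calcium-NFAT genes and 5 and 19 for the germinal centre signature. By limma 8656 of 12572 genes differed, 3788 higher in HBL-1 and 4868 higher in HT. The median over all genes was -0.11, and line and chip cannot be told apart in this comparison.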

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

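The tests of the splits, of the stress genes and of the mitosis genes in this part were laid down before their results were seen, and the list tests at 36 h were added after the data had been seen. The response to cyclosporin A differed between the lines by a test of the difference itself for 522 genes. Higher changes in HBL-1 were found for NLRP7 (1.92), VPREB3 (1.62), NSG1 (1.54), ATP9A (1.52), P3H3 (1.503), LTB (1.47), FXYD6 (1.36), SLC43A2 (1.28), TMEM132A (1.26) and SUSD3 (1.23). Lower changes were found for GPRC5C (-1.91), SOCS3 (-1.63), DEPP1 (-1.35), GAS6 (-1.34), SPNS3 (-1.16), BSPRY (-1.14), LYSMD2 (-1.13), CHAC1 (-1.11), IL4I1 (-1.09) and CCL3L3 (-1.08). NSG1, FXYD6, GPRC5C, SOCS3, DEPP1, GAS6, SPNS3, BSPRY, LYSMD2, IL4I1 and CCL3L3 were above background on 0 of 3 HT DMSO arrays, NLRP7 on 1 of 3 there and CHAC1 on 0 of 3 HBL-1 DMSO arrays, so a fall in that line could not be measured. Of the lists, median differences were -0.29 for the integrated stress response, 0.18 for B-cell identity, -0.12 for calcium-NFAT genes, -0.21 for cholesterol biosynthesis, -0.046 for DNA replication, -0.056 for mitosis, 0.16 for the germinal centre signature, -0.07 for hypoxia and glycolysis, 0.42 for MHC class II and -0.17 for NF-kB targets. With 12 and 24 h alone, 246 genes differed, CHAC1 (0.065) and the lists of the integrated stress response (-0.04), cholesterol biosynthesis (0.039), B-cell identity (0.081) and mitosis (-0.001) were not past the threshold, and hypoxia turned to 0.091. With an estimated correlation, DNA replication (adjusted p = 0.101) and hypoxia and glycolysis (adjusted p = 0.15) were not past the threshold. Among the 9416 genes above background on all DMSO arrays of both lines 470 differed, and the calcium-NFAT list was no longer past camera (median -0.005, adjusted p = 0.149), while the median of the NF-kB targets was -0.038 (adjusted p = 0.0355). Of 100 splits of the arrays, 2 gave as many genes as the real one, that one included. The median of the other splits was 0 genes. Most splits mixed time points within groups, which widens the spread. The share therefore cannot separate an effect of CsA from differences between time points. The highest other split called 1419 genes. It took the 3 HT arrays at 36 h as controls, which points to a structure of the samples, namely the distance of HT at 36 h from the other times.

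Changes between 12 h and 36 h were found for 1358 genes in HBL-1 and 3788 in HT. Each comparison has 10 splits of its arrays, too few for a share under 0.05. The real split gave the most genes in both, and the highest other split gave 2 in each. Among probes that the annotation pairs with no single gene, 7034 were tested, and 62 were past the threshold for the HBL-1 mean and 119 for the HT mean.

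The integrated stress genes were higher in HT at 36 h, with a median log2 fold change of 0.72 and quartiles of 0.43 and 1.46 over 32 genes. Unequal value distributions of the arrays do not explain it, since the median was 0.71 after quantile normalization within the line. Time in culture acting alike in both lines is not consistent with the HBL-1 value at 36 h, a median of -0.011 with quartiles of -0.19 and 0.15. Time in culture in HT itself stays open, since 0 DMSO arrays of HT were taken at 36 h and drug and time cannot be told apart there. A response of HT to the drug, or to nutrients used up by a denser culture, may be the source, and neither was tested.

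The mitosis genes were lower in HBL-1 at 48 h, with a median of -0.38 and quartiles of -0.47 and -0.29 over 43 genes. The separate chip of the 48 h arrays is not the whole cause, because 17 members were past the threshold downwards at 36 h, on the chip that also held the DMSO arrays. Time in culture stays open, since 0 DMSO arrays of HBL-1 were taken at 48 h and it cannot be told apart from the drug. Slower growth under the drug is a biological explanation that may apply and was not tested.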

How the results depend on the processing

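Quantile normalization over all arrays, means over 2 time points, the mean of all probes of a gene and the limit to genes above background in DMSO were chosen after the data had been seen; the other alternatives were planned. Named genes kept direction and side of the threshold in 11253 comparisons with an alternative other than leaving out 1 array, were no longer past it in 483, newly past it in 216 and reversed in 10. Lists did so in 2283, 32, 55 and 3. With 1 array left out, genes kept both in 9201, were no longer past it in 552 and newly past it in 99, and lists in 1907, 3 and 10. Several alternatives cannot change the direction of a gene. These are robust moderation, other filters, all probes kept apart, only the arrays compared and, within a line, the replicate block. Genes that were not past the threshold in either setting also count as kept. The tallies include the bead-level values, whose match used the compared values. They are therefore a description and no measure of robustness. The cause of a change was not tested except where stated.

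HT at 24 h (659 genes) gave 1036 with median centring, 210 with quantile normalization within the line, 208 over all arrays, 230 with bead-level values, 264 with their background correction and 53 with only the arrays compared. HBL-1 at 12 h (213) gave 48 with only the arrays compared and 138 with robust moderation and no trend, and its split of 143 up and 70 down became 177 and 140 with bead-level values. HBL-1 at 24 h (309) gave 585 with array weights, and 36 h against 12 h (1358) gave 666 with only the arrays compared, where fewer arrays estimate the spread. The lists called between the lines in DMSO went from 10 to 16 with no filter on dim probes.

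A minimum of 1.5-fold, which can only remove genes, left 91, 143, 507 and 491 genes in HBL-1 at 12, 24, 36 and 48 h, 172 for its mean, 326 for 36 h against 12 h, 155, 231 and 1015 in HT at 12, 24 and 36 h, 93 for its mean, 1348 for 36 h against 12 h and 260 for the line difference. With 12 and 24 h alone the HBL-1 mean gave 376 genes and the HT mean 322, of which 191 were among its 807, and 5 lists where it had 8. The line difference (522) gave 246, with CHAC1 (0.065), PMAIP1 (0.098), MVD (0.021) and the hypoxia list (0.091) reversed. Reversal of a list went by its camera direction, and the median of the cholesterol list changed sign there too. In HT, EGR1 (-0.73), PMAIP1 (-0.062), BTG1 (-0.17), SLC2A3 (-0.24), the cholesterol list (-0.055) and the hypoxia list (-0.10) then reversed, as the 36 h arrays that raised them were absent. With the mean of all probes, IL10 (-0.60) and PUS1 (-0.033) at 48 h and MCL1 (-0.009) between 12 h and 36 h in HBL-1 reversed, as their probes differed in sign.

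With 1 array left out, counts ran from 85 to 423 in HBL-1 at 12 h, 187 to 223 at 24 h, 768 to 1384 at 36 h, 953 to 1155 at 48 h, 377 to 766 for its mean and 485 to 1451 for 36 h against 12 h. In HT they ran from 290 to 400 at 12 h, 217 to 871 at 24 h, 2427 to 2771 at 36 h, 310 to 1032 for the mean and 3061 to 3385 for 36 h against 12 h. They ran from 287 to 616 for the line difference and 8322 to 8413 for the lines in DMSO. Lists ran from 10 to 12 at 48 h, 12 to 12 for the HBL-1 mean, 7 to 9 for the HT mean, 9 to 11 for the difference and 10 to 10 in DMSO. A replicate block gave 675 genes for the HBL-1 mean and 834 for the HT mean. Replicate numbers did not pair the arrays, since 12 of 27 correlated best with their own number. Values at background limit folds to lower bounds.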

Other observations

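The test of the falls in HT at 24 h was chosen only after that result was seen, while the splits were planned. In HT at 24 h, 73.4% of genes past the threshold were falls. Unequal value distributions of the arrays are consistent with this excess, since the share was 40.5% after quantile normalization within the line. The 75th percentile of the 24 h arrays was 6.01 to 6.14 on the log2 scale and that of the DMSO arrays 6.34 to 6.39. Whether the lower percentile has a technical or a biological source was not tested.

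Splits of the arrays compared were counted for each comparison. Of 100 splits, 2 gave as many genes as the real one for the HBL-1 mean (660) and 4 for the HT mean (807), the real split included. The median of the other splits was 0 genes in both. Most splits mixed time points within groups, which widens the spread. These shares therefore cannot separate an effect of CsA from differences between time points. The highest other split set the 3 arrays at 36 h apart in HBL-1 (1664 genes) and the 3 arrays at 12 h apart in HT (1174 genes), which points to a structure of the samples, the time points. The comparisons of 3 arrays with 3 have 10 splits, too few for a share under 0.05, and in each the real split alone (1 of 10) gave its count. For HBL-1 the real and highest other counts were 213 and 53 at 12 h, 309 and 0 at 24 h, 1587 and 0 at 36 h and 1493 and 0 at 48 h. For HT they were 549 and 3 at 12 h, 659 and 15 at 24 h and 3194 and 1 at 36 h. For the lines in DMSO they were 8656 and 0.

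Genes with more than 1 probe above the filter gave a check within the arrays. Other probes of the genes called shared their sign in 72.2% to 94.1% of cases over the comparisons and directions.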
